A study of Mus musculus with 6 samples.

How the data were processed

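The data were 6 small RNA libraries of exosomes from cultured mouse skin cells, 3 from epidermal stem cells (ESC) and 3 from dermal fibroblasts (Fb), grouped by their titles. Per the labels' protocols, culture medium was cleared, filtered, concentrated and ultracentrifuged, RNA was purified on columns, and libraries were built with the CleanTag small RNA kit and size-selected on a gel. Per the submitters' processing notes, FastQC and cutadapt were used and the genome build was GRCm38. The aligner, the counting tool, the use of strand and the treatment of reads that match several genes are not given in the sources used here.

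The deposited values were estimated counts of reads per annotated non-coding RNA. Of the nonzero values 82.6% to 92.2% were fractional in a library. Each file listed 16310 RNAs, of which 1964 were mature miRNAs (named with the prefix mmu-), 1226 miRNA hairpins, 471 tRNA genes and 12649 genes of other classes. RNA classes and positions came from GENCODE M21, which has the build of the files and named 12291 of those other genes. Reads per tRNA gene, per other member of near-identical families and per gene overlapping another depend on how matching reads were divided and are uncertain. Estimated counts were rounded to whole numbers before the count models.

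Class shares were computed as percent of assigned reads and compared with exact two-sided permutation tests (scipy 1.17.1) with Benjamini-Hochberg adjustment over the classes, which cannot go below p = 0.1 with 3 against 3 libraries. Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, group as the only term, Benjamini-Hochberg adjusted p of 0.05), once on mature miRNAs with their total as library size and once on all RNAs. Positive log2 fold changes mean higher in ESC exosomes. CPM of a miRNA is relative to mature miRNA reads unless stated otherwise. The reads carry no molecular identifiers, so intervals (exact Clopper-Pearson, 95%) and the floor of 3 reads per library cover counting error only. That floor was 1.97 to 2.15 CPM of miRNA reads in ESC and 16.9 to 61.2 CPM in Fb libraries, so a low miRNA was harder to detect in Fb exosomes. Nothing in the labels ties a library to one animal, so p-values measure the spread between these libraries.

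Before the data were examined, 18 miRNA lists with 172 members, 7 mRNA lists and the rule for the RNAs named were fixed. The miRNA lists were epithelial, miR-183 cluster, mesenchymal, HOX-cluster, Dlk1-Dio3, let-7, miR-17~92, miR-29, miR-34, miR-15 and miR-16, miR-23, miR-27 and miR-24, inflammation and wound, Sfmbt2 intron, haematopoietic, endothelial, muscle, neural and pigment-cell, and liver and serum miRNAs. They were tested with limma 3.58.1 (camera with a preset correlation of 0.01 and with an estimated one, and fry) on log2 CPM with a prior count of 2. The mRNA lists, 52 genes of keratinocytes, fibroblasts, melanocytes, immune, endothelial, fat and red cells, were not measured, since 0 of them had values in these non-coding RNA tables.

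The rule took the 10 miRNAs with the largest fold in each direction that passed with non-overlapping groups and at least 100 CPM, the 10 most abundant miRNAs of each group, up to 4 members per list by p with at least 10 CPM, by the same criteria up to 3 RNAs per direction of each other class with at least 20 members tested, and markers of other cell types at 100 CPM or more in any library. It gave 85 RNAs, 71 of them miRNAs, of which the text describes a part.

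The alternatives were DESeq2 1.42.0, limma-trend, upper-quartile factors, library totals alone, other count filters, a fold threshold of 2, other library sizes for miRNAs, the replicate number as a block, and leaving out each library in turn. Sums over tRNA genes, over miR-199a-3p and miR-199b-3p and over miR-486a-5p and miR-486b-5p, a fit without tRNA genes, size factors from the 100 most abundant RNAs, and miRNAs as shares of all assigned reads were added after the data were seen.

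The fits were tested on counts simulated from one mean profile over all libraries, with some RNAs changed by known folds. Scaling between groups of unlike composition was therefore not tested. For miRNAs edgeR recovered 68.9% of 45 miRNAs changed 4-fold and 97.5% of 40 changed 16-fold, of 347 tested, with 0 calls among 262 unchanged ones, where DESeq2 made 3. For all RNAs, with 2996 tested, edgeR recovered 4.2% of 24 changed 4-fold and 51.4% of 35 changed 16-fold. There DESeq2 recovered 91.4% of those changed 16-fold, with 29.5% of its calls on unchanged RNAs. The camera test gave an unadjusted p = 6.86e-08 to a shifted list, and 9 of 200 unshifted lists had p under 0.05. Lists whose members vary together were not simulated, so the preset correlation was not tested for them. In the data the estimated correlation within a list ranged from -0.377 (Sfmbt2 intron) to 0.836 (miR-34), with 0.469 for the mesenchymal list. By a chi-square test of miRNA counts no pair of libraries agreed within sampling noise, so none was a copy of another. The test cannot tell separate cultures from repeat libraries of one culture. Each library was counted as 1 sample, as the labels call them biological replicates.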

Results

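Small RNA libraries were made from exosomes, the small vesicles that cells release into their medium, collected from cultured mouse epidermal stem cells (ESC) and dermal fibroblasts (Fb) of dorsal skin. Each cell type was represented by 3 libraries, which the labels call biological replicates. The comparison addressed how the small non-coding RNA content of ESC exosomes differed from that of Fb exosomes. Per the labels' protocols, the ESC came from C57BL/6 mice and were kept in serum-free keratinocyte medium. The Fb came from older db/db mice, a strain with obesity and diabetes, and grew in medium with serum before a serum-free collection period, although the strain label reads C57BL/6 for every library. Cell type, donor mice, age and medium therefore changed together between the groups.

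Reads assigned to annotated RNAs numbered 9894485 to 11149046 per ESC library and 6914504 to 8691350 per Fb library. Mature miRNAs, the short guide RNAs of gene silencing, received 1392859 to 1522604 reads in the ESC libraries but only 49019 to 177990 in the Fb libraries. The number of mature miRNAs with at least 10 reads was 325 to 338 in ESC and 169 to 221 in Fb exosomes. Pearson correlations of log2 CPM across miRNAs with a mean of at least 10 reads, which are not independent of one another, were 0.965 to 0.982 between ESC libraries and 0.776 to 0.925 between Fb libraries. Between the groups they were 0.581 to 0.651.

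ESC exosomes carried a larger miRNA share than Fb exosomes in every library. Mature miRNAs made up 14.0% ± 0.710 (SD, n = 3) of assigned reads in ESC and 1.46% ± 0.751 (SD, n = 3) in Fb exosomes, a ratio of 9.60. Small nuclear RNAs, the RNA parts of the splicing machinery, followed the same direction at 3.20% ± 0.262 against 0.267% ± 0.0385. Y RNAs, which bind the Ro60 protein, held 0.619% ± 0.0502 in ESC and 0.210% ± 0.0531 in Fb exosomes. Nearly all of these reads were of Rny1, at 0.617% ± 0.0501 and 0.207% ± 0.0531. The other Y RNA, Rny3, averaged 0.00192% ± 0.000149 in ESC and 0.00325% ± 0.00193 in Fb exosomes. Long non-coding RNAs (lncRNAs) as a class were higher in Fb exosomes, with 2.42% ± 0.158 in ESC and 12.5% ± 4.07 in Fb exosomes.

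tRNA genes took most reads in both groups, with 79.3% ± 0.590 in ESC and 84.9% ± 4.54 in Fb exosomes. Ribosomal RNA held 0.111% ± 0.0205 in ESC and 0.373% ± 0.144 in Fb exosomes, and miRNA hairpins 0.0175% ± 0.00357 and 0.102% ± 0.0331. Annotated miscellaneous RNAs were at 0.128% ± 0.0203 in ESC and 0.0220% ± 0.00353 in Fb exosomes, and mitochondrial RNAs at 0.0179% ± 0.00130 and 0.00635% ± 0.000723. Genes of other or unmatched classes held 0.0955% ± 0.00176 and 0.191% ± 0.101. In each of these classes, and for miRNAs, small nuclear RNAs, Y RNAs and lncRNAs, every ESC library lay on one side of every Fb library, with an exact permutation p = 0.1, the smallest that 3 against 3 libraries allows, and an adjusted exact permutation p of 0.11 over the 11 classes compared. Chance alone separates 10% of classes in this way. Small nucleolar RNAs overlapped between the groups, at 0.0554% ± 0.00619 and 0.0360% ± 0.0162 (exact permutation p = 0.3), and their direction turned when tRNA reads were left out of the total.

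Within the Fb group the miRNA share was lowest in replicate 1, at 0.613% (exact 95% binomial interval 0.608 to 0.619), against 2.05% (2.04 to 2.06) in replicate 2 and 1.72% (1.71 to 1.73) in replicate 3. The 10 lncRNA genes with the most Fb reads held at least 70.65% of the lncRNA reads in each Fb library.

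**Figure D1:**
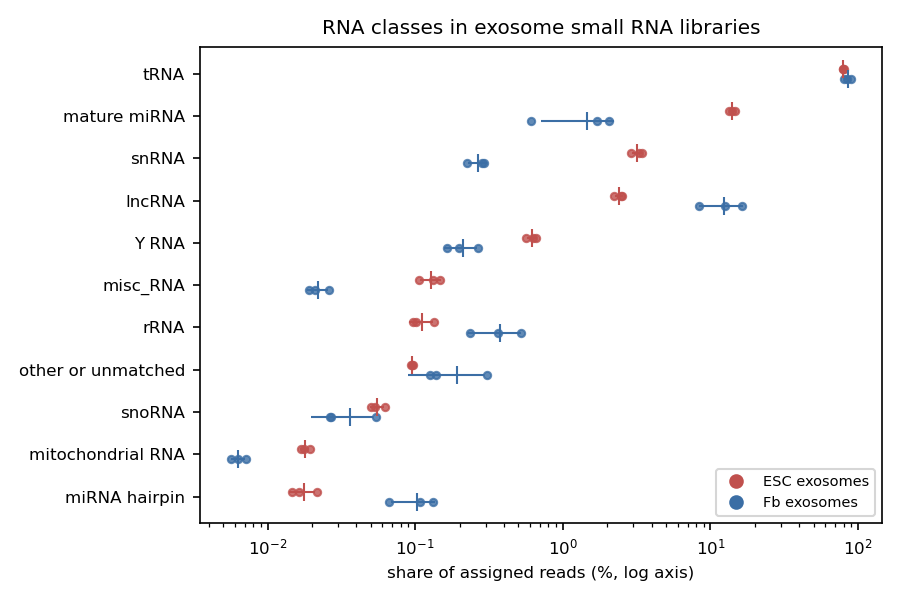
Share of assigned reads, in percent on a log axis, taken by each RNA class in exosome libraries from ESC (red) and Fb (blue). Points are the 3 libraries of a group, ticks their mean and lines 1 SD; mature miRNAs averaged 14.0% in ESC and 1.46% in Fb exosomes.

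The tRNA reads of Fb exosomes were spread over more tRNA types. Glycine tRNAs held 83.6% ± 0.472 (SD, n = 3) of tRNA reads in ESC and 58.9% ± 4.68 in Fb exosomes. Glutamate tRNAs held 15.7% ± 0.399 and 23.0% ± 5.04. Anticodons within these sums went opposite ways. Of tRNA reads, glycine CCC held 66.7% ± 3.45 in ESC and 22.5% ± 1.82 in Fb exosomes and glycine GCC 17.0% ± 3.04 and 36.4% ± 3.46, while glutamate CTC held 13.4% ± 0.206 and 22.2% ± 4.72 and glutamate TTC 2.29% ± 0.396 and 0.873% ± 0.493. These 4 anticodons, named after their values were seen, did not overlap between the groups (exact permutation p = 0.1, adjusted exact permutation p = 0.1425 each), but their split depends on how reads of similar genes were divided. Valine tRNAs were at 0.393% ± 0.131 in ESC and 14.2% ± 2.61 in Fb exosomes, lysine tRNAs at 0.144% ± 0.0265 and 2.28% ± 1.29, and histidine tRNAs at 0.0690% ± 0.00307 and 0.995% ± 0.345.

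For these 5 amino acids every ESC library was separate from every Fb library, each at an exact permutation p = 0.1 and an adjusted exact permutation p of 0.133 over the 24 tRNA groups compared. Other tRNA groups, such as asparagine and tryptophan tRNAs, were separate as well. When tRNA genes were summed by amino acid and fitted with all other RNAs, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called valine (log2 fold change -7.04, SE 1.70, adjusted p = 0.0274), lysine (-6.38, SE 1.72, adjusted p = 0.0416) and histidine tRNAs (-6.11, SE 1.56, adjusted p = 0.0332) higher in Fb exosomes. Glycine (-1.47, SE 1.47) and glutamate tRNAs (-2.69, SE 1.50) did not pass, at edgeR adjusted p = 0.680 and 0.362. Other sums passed on the Fb side with larger folds, such as initiator methionine (-9.23), threonine (-8.40) and arginine tRNAs (-8.29). All amino acid sums fitted had negative log2 fold changes, so the direction was not particular to valine, lysine and histidine. For glycine the sign went against the shares, since glycine tRNAs held more of the tRNA reads in ESC exosomes. The size of these folds depends on the scaling. With single tRNA genes in the fit of all RNAs, their median log2 fold change was -5.066 with TMM factors and -3.555 with library totals alone. The sums were fitted with TMM factors only, so neither their folds nor the glycine sign was tested under another scaling. Near-identical tRNA genes share reads, so single tRNA genes are uncertain, and the sums were chosen for that reason after the data were seen and fitted with all 6 libraries only.

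**Figure D2:**
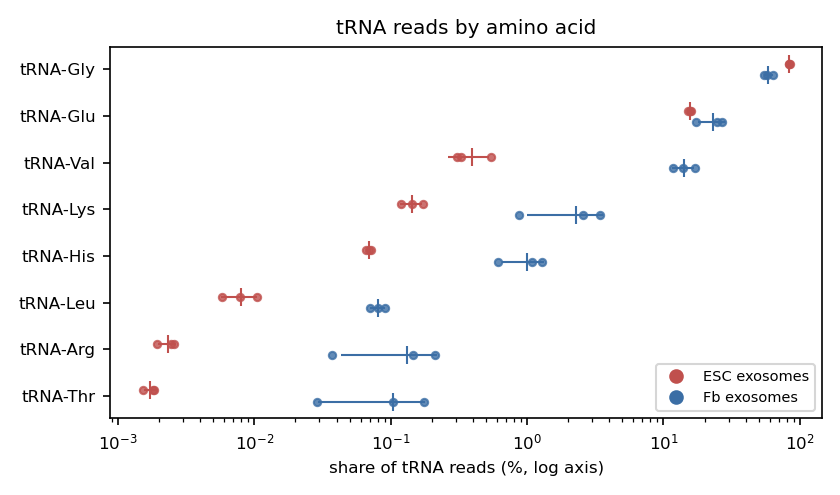
Share of tRNA reads, in percent on a log axis, for 8 amino acids in ESC (red) and Fb (blue) exosomes. Points are the 3 libraries of a group, ticks their mean and lines 1 SD; valine tRNAs averaged 0.393% in ESC and 14.2% in Fb exosomes.

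Among mature miRNAs, epithelial miRNAs were higher in ESC exosomes and mesenchymal and imprinted-cluster miRNAs in Fb exosomes. miR-182-5p was at 105968 ± 4323 CPM of miRNA reads (reads scaled to one common total per library; SD, n = 3) in ESC against 6854 ± 1573 CPM in Fb exosomes. miR-143-3p, a miRNA of smooth muscle and stromal cells, was at 131 ± 4.89 CPM in ESC against 89552 ± 10841 CPM in Fb exosomes. Of 325 miRNAs tested, 161 passed an adjusted p of 0.05, 71 higher in ESC and 90 higher in Fb exosomes, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The groups did not overlap in 158 of these and in 199 (61.2%) of the 325, where chance gives 10%. As shares of all assigned reads, a measure added after the data were seen, the 71 miRNAs were higher in every ESC library. Of the 90 only 34 were higher in every Fb library, 34 overlapped and 22 were higher in every ESC library. Of the miRNAs that did not pass, 150 were higher in every ESC library, 0 in every Fb library and 14 overlapped. The larger miRNA share of ESC reads enters this measure by construction, so it adds nothing to the 71 calls.

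These fold changes compare shares of miRNA reads, and their median was -0.11. Scaling by miRNA totals alone moved the median to -0.52 and the calls to 52 higher in ESC and 103 in Fb exosomes. Leaving the 3 most abundant miRNAs out of the library size moved it to 0.30 with 90 and 75 calls, and fitting the miRNAs with all other RNAs moved it to 1.15 with 74 and 22 calls when adjusted over the 307 miRNAs tested there, of which 60 were among the 161. Adjusted over all RNAs of that fit, 53 and 16 passed. Of the 161, no miRNA that was tested under one of these scalings changed sign there. The number of calls was 103 without Fb replicate 3 and 107 without ESC replicate 3.

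All 7 tested members of the epithelial list, the miR-200 family with miR-203 and miR-205, were higher in ESC exosomes, and 7 passed when adjusted over the list alone. The miR-200 family holds cells in the epithelial state by repressing Zeb1 and Zeb2, and miR-205 marks stratified epithelium. miR-200c-3p was at 13135 ± 758 CPM in ESC and 411 ± 280 CPM in Fb exosomes (log2 fold change 5.50, SE 0.47, edgeR adjusted p = 1.24e-04). miR-200b-3p (log2 fold change 5.51, SE 0.54), miR-200a-3p (4.20, SE 0.40) and miR-429-3p (3.34, SE 0.48) moved in the same direction. miR-200b-5p, the other arm of its hairpin, had 1257 reads over the ESC libraries and 2 over the Fb libraries, both in replicate 3, a rate ratio of 49.5 (exact 95% counting interval 13.7 to 409). The gene of miR-200b lies on chromosome 4 (156055681 to 156055750, GRCm38, minus strand) within the annotated span of Ttll10, as do those of miR-200a and miR-429.

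miR-205-5p was at 28761 ± 5640 CPM in ESC and 6742 ± 2651 CPM in Fb exosomes (log2 fold change 2.44, SE 0.43, edgeR adjusted p = 0.00342), and missed the threshold without Fb replicate 3, as miR-203-3p did (edgeR adjusted p = 0.0523 for both). The epithelial members together held 6.86% ± 0.772 of miRNA reads in ESC and 1.06% ± 0.339 in Fb exosomes. The list passed limma's camera test at a preset correlation (adjusted p = 8.65e-04), with an adjusted p = 0.137 with an estimated correlation.

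The cluster of miR-183, miR-96 and miR-182, known from sensory and epithelial cells, was higher in ESC exosomes for all 3 members, and 3 passed when adjusted over the list alone. miR-182-5p had a log2 fold change of 4.37 (SE 0.27, edgeR adjusted p = 3.36e-05) and miR-183-5p one of 4.67 (SE 0.31, edgeR adjusted p = 4.46e-05). miR-96-5p was at 76.9 ± 5.48 CPM in ESC exosomes and had 0 reads in every Fb library, so it was at least 2.23-fold higher in ESC against a floor of 3 reads per library. The cluster held 12.6% ± 0.462 of miRNA reads in ESC and 0.795% ± 0.191 in Fb exosomes. It passed limma's camera test (adjusted p = 0.00497), with an adjusted p = 0.218 with an estimated correlation.

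All 11 members of the mesenchymal list (miR-199 and miR-214, miR-143 and miR-145, and miR-152) were higher in Fb exosomes, and 11 passed when adjusted over the list alone. miR-143-3p had a log2 fold change of -9.03 (SE 0.38, edgeR adjusted p = 7.31e-06). Its gene lies on chromosome 18 (61649196 to 61649258, GRCm38, minus strand), next to that of miR-145a. miR-199a-3p and miR-199b-3p share one mature sequence, and their split varied, with 9.77% and 1.40% of miRNA reads in Fb replicate 1 but 1.73% and 15.6% in Fb replicate 3. Their sum was 0.00564% ± 0.00142 of miRNA reads in ESC and 16.1% ± 4.40 in Fb exosomes (log2 fold change -11.10, SE 0.52, edgeR adjusted p = 4.77e-06 in a fit added after the data were seen). Counted singly, miR-199a-3p missed the threshold without ESC replicate 2 or 3 or Fb replicate 3 (edgeR adjusted p = 0.0923, 0.101 and 0.0723) and by limma-trend (limma adjusted p = 0.180). As shares of all assigned reads, the groups overlapped for miR-199a-3p and for miR-152-3p, at 74.3 ± 2.02 CPM in ESC and 54.9 ± 42.4 CPM in Fb exosomes.

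miR-214-3p was at 1.35 ± 1.32 CPM in ESC and 2684 ± 357 CPM in Fb exosomes (log2 fold change -10.40, SE 0.86). miR-214-5p and miR-145a-3p had 0 reads in every ESC library and were at least 199-fold and at least 178-fold higher in Fb exosomes, at a floor of 3 reads per library. miR-145a-5p had 3 reads over the ESC libraries and 1995 over the Fb libraries, a rate ratio of 8452 (exact 95% counting interval 2888 to 41017). miR-199a-5p had 2 and 1260 reads, a ratio of 8007 (2212 to 66187). The mesenchymal members together held 0.0722% ± 0.00434 of miRNA reads in ESC and 26.5% ± 5.97 in Fb exosomes. Their median log2 fold change was -10.40, or -9.03 with members at 0 reads set to their bound. The list passed limma's camera test (adjusted p = 2.16e-06), with an adjusted p = 0.300 with an estimated correlation.

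Of the imprinted Dlk1-Dio3 cluster on chromosome 12, a large miRNA cluster expressed from the maternal chromosome, 19 of 56 members were tested. Of these, 18 were higher in Fb exosomes and 1, miR-411-5p, did not pass, with the same count of 18 when adjusted over the list alone. With no count filter 46 members were tested, of which 30 were higher in Fb exosomes and 16 did not pass. miR-541-5p was at 5.92 ± 0.769 CPM in ESC and 862 ± 125 CPM in Fb exosomes (log2 fold change -6.78, SE 0.38, edgeR adjusted p = 3.36e-05). miR-434-3p (log2 fold change -8.17, SE 0.51), miR-127-3p (-5.49, SE 0.40) and miR-299a-3p (-5.85, SE 0.48) moved in the same direction. miR-341-3p had 1 read over the ESC libraries and 58 over the Fb libraries (ratio 737, exact 95% counting interval 127 to 29611). miR-127-3p and miR-434-3p derive from genes at 109592846 to 109592915 and 109594506 to 109594599 of chromosome 12 (GRCm38), opposite the Rtl1 gene. The cluster was a small part of the miRNA reads, at 0.00725% ± 0.00117 in ESC and 0.453% ± 0.0533 in Fb exosomes. It passed limma's camera test (adjusted p = 5.49e-09), with an adjusted p = 0.0330 with an estimated correlation. That last p was 0.0417 with upper-quartile factors, 0.0807 with library totals alone, 0.126 with no count filter and 0.102 to 0.270 when any one library was left out. As shares of all assigned reads, the groups overlapped for miR-369-3p, miR-433-3p and miR-323-3p, and the last missed the threshold without Fb replicate 3 (edgeR adjusted p = 0.276).

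**Figure D3:**
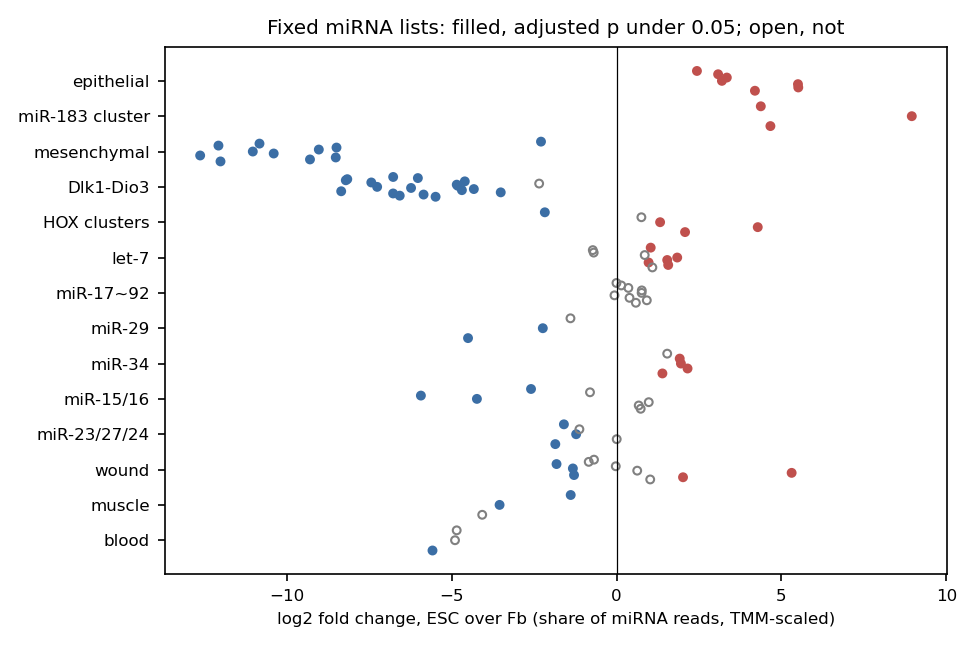
Fitted log2 fold change (ESC over Fb exosomes) of each tested miRNA in 14 lists; red and blue points passed an adjusted p of 0.05 in edgeR's quasi-likelihood test and open points did not. All 11 mesenchymal and 18 of 19 Dlk1-Dio3 members passed on the Fb side; folds of miRNAs with 0 to 3 reads in a group are not bounds.

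miRNAs from the HOX clusters, the homeobox gene clusters that set position along the body, were divided. miR-10b-5p was one of the most abundant miRNAs of ESC exosomes at 94437 ± 14569 CPM, against 6781 ± 3974 CPM in Fb exosomes (log2 fold change 4.28, SE 0.42, edgeR adjusted p = 2.16e-04). miR-10a-5p (log2 fold change 2.08, SE 0.33) and miR-196a-5p (1.32, SE 0.36) were also higher in ESC exosomes, and miR-615-3p (-2.18, SE 0.34) was higher in Fb exosomes. Over the 5 members tested, 3 were higher in ESC, 1 in Fb and 1, miR-196b-5p, did not pass, also when adjusted over the list alone. miR-196a-5p missed the threshold without Fb replicate 3 (edgeR adjusted p = 0.118).

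The let-7 family, abundant in differentiated cells, held 17.0% ± 0.0600 of miRNA reads in ESC and 11.9% ± 0.556 in Fb exosomes. Of 9 members, 5 were higher in ESC exosomes and 4 did not pass, as when adjusted over the list alone. let-7b-5p (log2 fold change 1.57, SE 0.24), let-7c-5p (0.97, SE 0.26), let-7d-5p (1.54, SE 0.38), let-7e-5p (1.84, SE 0.51) and miR-98-5p (1.04, SE 0.30) passed. The others were let-7a-5p (1.09, SE 0.54), let-7f-5p (0.85, SE 0.42), let-7g-5p (-0.69, SE 0.65) and let-7i-5p (-0.72, SE 0.37). let-7c-5p missed the threshold without Fb replicate 3 (edgeR adjusted p = 0.132), let-7d-5p without ESC replicate 3 (0.0606) let-7e-5p without ESC replicate 2 or 3 (0.0508 and 0.0773) and miR-98-5p without ESC replicate 1 or 3 or Fb replicate 3 (0.0798, 0.0748 and 0.0854). The count on the ESC side was thus 2 without ESC replicate 3 and 3 without Fb replicate 3. Without Fb replicate 1 it was 7, and let-7g-5p and let-7i-5p passed on the Fb side (edgeR adjusted p = 0.00801 for both). With library totals alone 1 member passed on the ESC side and let-7i-5p on the Fb side (edgeR adjusted p = 0.0239).

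The p53-regulated miR-34 family had 4 of 5 members higher in ESC exosomes, and 5, with miR-34c-3p, when adjusted over the list alone. miR-34b-3p was at 1215 ± 165 CPM in ESC and 408 ± 114 CPM in Fb exosomes (log2 fold change 1.95, SE 0.35, edgeR adjusted p = 0.00342). miR-34b-5p, miR-34c-5p and miR-34a-5p missed the threshold without ESC replicate 3 (edgeR adjusted p = 0.0524, 0.0699 and 0.0589) and without Fb replicate 3 (0.0802, 0.179 and 0.194), and miR-34a-5p also without ESC replicate 1 (0.0503). With library totals alone 2 members passed, and by limma-trend miR-34b-5p did not (limma adjusted p = 0.0740). None of the 9 members tested of miR-17~92 and its paralogs, which promote proliferation, passed edgeR's test over all miRNAs or when adjusted over the list alone, and 0 had an unadjusted p under 0.05. miR-92a-3p, its most abundant member, was at 35732 ± 1706 CPM in ESC and 29577 ± 20808 CPM in Fb exosomes (log2 fold change 0.76, SE 0.43). It did not pass with DESeq2 or limma, and passed on the ESC side without Fb replicate 1 (log2 fold change 1.39, edgeR adjusted p = 0.00255) and with no count filter (1.25, edgeR adjusted p = 0.00947).

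The miR-29 family, which represses collagen genes, had 2 of 3 members higher in Fb exosomes, also when adjusted over the list alone. miR-29a-3p was at 358 ± 61.5 CPM in ESC and 10255 ± 4808 CPM in Fb exosomes (log2 fold change -4.50, SE 0.56, edgeR adjusted p = 7.17e-04). miR-29b-3p had a log2 fold change of -2.24 (SE 0.55) and missed the threshold without Fb replicate 2 (edgeR adjusted p = 0.0644), while miR-29c-3p passed on the Fb side without Fb replicate 1 (edgeR adjusted p = 0.00163). In the family of miR-15, miR-16, miR-322 and miR-503, 3 of 7 members were higher in Fb exosomes, also when adjusted over the list alone, namely miR-497a-5p (log2 fold change -5.93, SE 0.97), miR-195a-5p (-4.24, SE 0.98) and miR-503-5p (-2.59, SE 0.43). miR-16-5p did not pass, at 10180 ± 1187 CPM in ESC and 6534 ± 2991 CPM in Fb exosomes, but was higher in ESC exosomes without Fb replicate 1 (log2 fold change 0.68, edgeR adjusted p = 0.0126), with upper-quartile factors (1.18, edgeR adjusted p = 0.0471) and with no count filter (1.45, edgeR adjusted p = 0.00566). It also passed by DESeq2 (DESeq2 adjusted p = 0.0414) and with the 3 most abundant miRNAs left out of the library size (edgeR adjusted p = 0.0392). miR-15b-5p passed on the ESC side without Fb replicate 2 (edgeR adjusted p = 0.0293). As shares of all assigned reads, the groups overlapped for miR-29a-3p, miR-29b-3p, miR-195a-5p, miR-497a-5p and miR-503-5p. miR-195a-5p had too few reads to be tested without any one ESC library or Fb replicate 2.

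The miR-23, miR-27 and miR-24 clusters had 3 of 5 members higher in Fb exosomes, also when adjusted over the list alone. miR-24-3p was at 8442 ± 259 CPM in ESC and 34290 ± 7307 CPM in Fb exosomes (log2 fold change -1.60, SE 0.24, edgeR adjusted p = 0.00162), but per assigned read it was higher in ESC, at 1183 ± 74.0 against 465 ± 184 CPM of all assigned reads. By that measure miR-27a-3p was also higher in every ESC library, and the groups overlapped for miR-23a-3p. miR-23a-3p (log2 fold change -1.86, SE 0.61) and miR-27a-3p (-1.23, SE 0.38) passed with all libraries, but missed the threshold without any one library other than Fb replicate 1 (edgeR adjusted p = 0.106 to 0.169 and 0.0944 to 0.220). Both also missed it with the 3 most abundant miRNAs left out of the library size (edgeR adjusted p = 0.0795 and 0.102), miR-23a-3p by limma-trend (limma adjusted p = 0.110) and miR-27a-3p with no count filter (edgeR adjusted p = 0.347). Without Fb replicate 2 their log2 fold changes were -1.16 and -0.745, and miR-27b-3p passed on the Fb side without Fb replicate 1 (edgeR adjusted p = 9.72e-04) and with library totals alone (0.0357).

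Among 10 inflammation and wound miRNAs, 2 were higher in ESC, 3 in Fb exosomes and 5 did not pass, as when adjusted over the list alone. miR-146a-5p, a brake on NF-kB signalling, was at 57231 ± 5143 CPM in ESC and 1994 ± 1031 CPM in Fb exosomes (log2 fold change 5.31, SE 0.38, edgeR adjusted p = 5.68e-05). miR-31-5p, active in wounded epidermis, was also higher in ESC exosomes (log2 fold change 2.02, SE 0.53), but not without ESC replicate 3 (edgeR adjusted p = 0.0517) or with library totals alone (0.0510). miR-132-3p (log2 fold change -1.29, SE 0.27), miR-212-3p (-1.82, SE 0.38) and miR-155-5p (-1.33, SE 0.38) were higher in Fb exosomes, although as shares of all assigned reads these 3 were higher in every ESC library. miR-155-5p missed the threshold without any one library other than Fb replicate 1 (edgeR adjusted p = 0.0595 to 0.155). miR-132-3p missed the threshold without ESC replicate 1 or 2 or Fb replicate 3 (edgeR adjusted p = 0.0639, 0.0593 and 0.0848), and miR-212-3p without ESC replicate 1 or Fb replicate 2 or 3 (0.0509, 0.0566 and 0.0554). With library totals alone 1 was higher in ESC and 5 in Fb exosomes, without Fb replicate 1 these were 4 and 5, and with no count filter 3 and 0. The list's median log2 fold change was -0.35 and its mean 0.30, and limma's camera test gave it the direction of ESC, so these differ in sign. miR-21a-5p, among the most abundant miRNAs of both groups, did not pass at 94494 ± 5114 CPM in ESC and 59365 ± 21952 CPM in Fb exosomes (log2 fold change 1.02, SE 0.39, edgeR adjusted p = 0.0679). It passed on the ESC side without ESC replicate 2 or Fb replicate 1 or 2 (edgeR adjusted p = 0.0464, 0.00119 and 0.0435), and with all libraries by DESeq2 (DESeq2 adjusted p = 0.0116), with upper-quartile factors (edgeR adjusted p = 0.0253), with no count filter (5.32e-04) and with the 3 most abundant miRNAs left out of the library size (0.0189).

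Of 3 tested miRNAs from the Sfmbt2 intron cluster, miR-669c-5p was higher in ESC exosomes (log2 fold change 3.01, SE 0.38) and 2 did not pass, also when adjusted over the list alone. Of these 2, miR-466f-3p, with 2 Fb reads, passed without Fb replicate 1 and miR-669a-5p without Fb replicate 2 (edgeR adjusted p = 0.0185 and 0.0423). With no count filter 3 of 12 were higher in ESC exosomes. Of the 15 lists with more than 1 tested member, 4 passed limma's camera test, and the others had adjusted p from 0.102 to 0.951. Of these 4, the Dlk1-Dio3 list alone passed with an estimated correlation (adjusted p = 0.0330, against 0.137, 0.218 and 0.300), and that call was lost when any one library was left out. With no count filter 9 lists passed at the preset correlation. As shares of all assigned reads, miR-615-3p and miR-206-3p were higher in every ESC library, and the groups overlapped for miR-22-3p and miR-133a-3p.

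Outside the lists, miR-672-5p was at 565 ± 36.3 CPM in ESC and 37.5 ± 38.8 CPM in Fb exosomes (log2 fold change 4.68, SE 0.56, edgeR adjusted p = 6.37e-04). miR-6239 was at 22.9 ± 6.35 CPM in ESC and 24685 ± 3943 CPM in Fb exosomes (log2 fold change -9.65, SE 0.41, edgeR adjusted p = 7.31e-06). miR-22-3p was at 3724 ± 204 CPM in ESC and 30789 ± 14726 CPM in Fb exosomes (log2 fold change -2.61, SE 0.40). miR-320-3p (log2 fold change 0.72, SE 0.58) and, of the wound list, miR-221-3p (-0.84, SE 0.45), both abundant, did not pass, but passed without Fb replicate 1 (edgeR adjusted p = 0.00555 and 0.00132). miR-320-3p also passed with no count filter (edgeR adjusted p = 0.0173) and miR-221-3p with library totals alone (0.0409). The 10 most abundant miRNAs of each library held 60.6% to 63.5% of its miRNA reads in ESC and 53.7% to 60.6% in Fb exosomes.

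**Figure D4:**
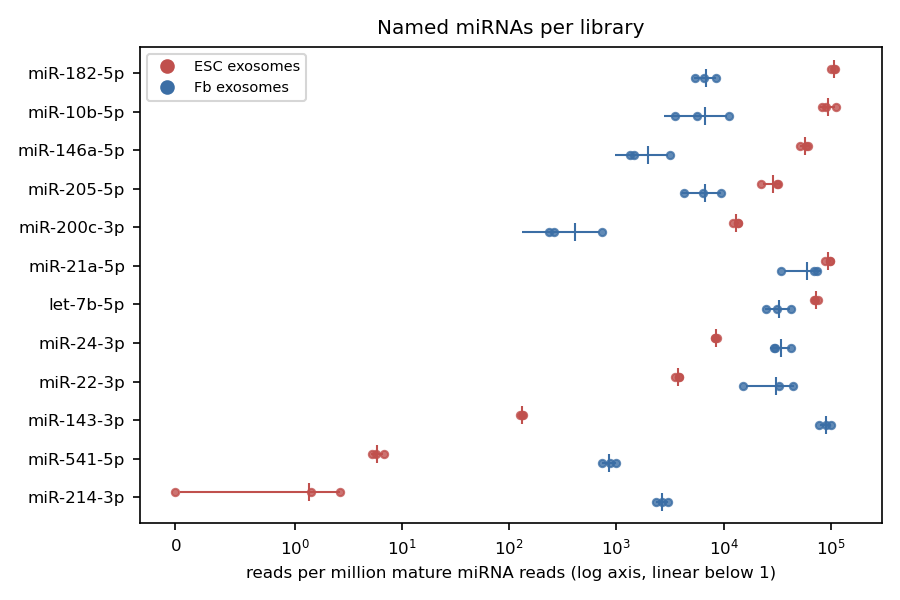
CPM of mature miRNA reads (log axis, linear below 1) of 12 named miRNAs in ESC (red) and Fb (blue) exosomes. Points are the 3 libraries of a group, ticks their mean and lines 1 SD; miR-143-3p averaged 131 in ESC and 89552 in Fb exosomes.

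Among miRNAs of other cell types, haematopoietic and erythroid miRNAs held 0.0243% ± 0.00547 of miRNA reads in ESC and 0.930% ± 1.14 in Fb exosomes, with 0.440%, 0.118% and 2.23% in Fb replicates 1, 2 and 3. miR-486a-5p and miR-486b-5p, which share one mature sequence and held most of these reads, did not pass when counted singly (edgeR adjusted p = 0.0686 and 0.118), and their split varied, with 0 and 314 reads in ESC replicate 1 but 456 and 0 in ESC replicate 3. Singly, miR-486a-5p passed on the Fb side without Fb replicate 2 (edgeR adjusted p = 0.0432) and by DESeq2 (DESeq2 adjusted p = 0.0135), miR-486b-5p without Fb replicate 1 (edgeR adjusted p = 0.0338), and both with no count filter. Their sum, fitted after the data were seen, was at 240 ± 54.1 CPM in ESC exosomes and 4264, 1146 and 22165 CPM in Fb replicates 1, 2 and 3, and was higher in Fb exosomes (log2 fold change -4.88, SE 1.09, edgeR adjusted p = 0.00825). It also passed without any one library, with a log2 fold change of -2.71 without Fb replicate 3, but overlapped between the groups as a share of all assigned reads. miR-142a-5p, a leukocyte miRNA, was the 1 member of 3 that passed, also when adjusted over the list alone, with 3 reads over the ESC libraries and 16 over the Fb libraries (ratio 67.8, exact 95% counting interval 19.4 to 363). It had too few reads to be tested without Fb replicate 1 or 3, and no member passed without the latter. With no count filter 4 of 7 members were higher in Fb exosomes.

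Of the muscle miRNAs, miR-206-3p (log2 fold change -1.39, SE 0.32) and miR-133a-3p (-3.55, SE 0.97) were higher in Fb exosomes and 1 of the 3 tested did not pass, but 3 passed when adjusted over the list alone. miR-206-3p missed the threshold without ESC replicate 1 or 2 or Fb replicate 2 or 3 (edgeR adjusted p = 0.0888, 0.0745, 0.0730 and 0.121), and miR-133a-3p without ESC replicate 1 or 2 or Fb replicate 1 (0.0611, 0.0677 and 0.0527). The remaining member, miR-1a-3p, had 53 reads in Fb replicate 1 against 1 and 0 in replicates 2 and 3, and its log2 fold change of -4.07 was 2.20 without Fb replicate 1. It passed without Fb replicate 2 (edgeR adjusted p = 0.0288) and with no count filter (4.39e-08), where miR-206-3p did not (0.208), and by DESeq2 (DESeq2 adjusted p = 0.0325). The endothelial miR-126a-5p (103 ± 23.5 CPM in ESC and 198 ± 131 CPM in Fb exosomes) and the liver and serum miR-192-5p (1444 ± 81.1 and 1778 ± 259 CPM) did not pass, also when adjusted over the list alone. No neural or pigment-cell miRNA had enough reads to be tested.

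When RNAs of all classes were fitted together with edgeR, 355 of 2999 passed, 109 higher in ESC and 246 higher in Fb exosomes. The lncRNAs gave 27 higher in ESC and 108 higher in Fb exosomes of 2240 tested, and the tRNA genes 4 and 82 of 157. Of 43 small nuclear RNA genes 18 were higher in ESC and 2 in Fb exosomes, of 54 small nucleolar RNA genes 2 and 20, and of 28 ribosomal RNA genes 0 and 10. The small nucleolar RNA calls went against the share of that class, which was 0.0554% in ESC and 0.0360% in Fb exosomes, and with library totals alone they were 6 and 4. Calls of annotated miscellaneous RNAs also went against their share, at 1 and 3 of 14 tested, and were 2 and 2 with library totals alone. The Y RNAs Rny1 (log2 fold change -0.26, SE 1.24) and Rny3 (-2.14, SE 0.78) did not pass (edgeR adjusted p = 0.957 and 0.126), with signs against the Y RNA share. The lncRNA calls were 14 and 44 by that scaling, and 1 and 74 of 1980 tested with size factors from the 100 most abundant RNAs. The small nuclear RNA gene Gm22970 was at 6926 ± 1033 CPM of assigned reads in ESC and 8.14 ± 2.73 in Fb exosomes (log2 fold change 8.09, SE 1.57, edgeR adjusted p = 0.0140). Rnu1a1, a U1 gene with near-identical copies, was at 4846 ± 1500 CPM in ESC exosomes and had 0 reads in every Fb library, where 3 reads would be 0.345 to 0.434 CPM. Without ESC replicate 1, 2 or 3 or Fb replicate 3 both genes missed the threshold, at edgeR adjusted p = 0.0826 to 0.0907 for Gm22970 and 0.0510 to 0.0728 for Rnu1a1.

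The lncRNA gene Gm16365, on chromosome 10 (39558496 to 39613682, GRCm38, minus strand) opposite Fyn and Traf3ip2, held 0.0126% ± 0.00340 of assigned reads in ESC and 3.93% ± 2.09 in Fb exosomes (log2 fold change -10.55, SE 2.35, edgeR adjusted p = 0.0199). D230017M19Rik, whose span holds small nuclear RNA genes, was higher in ESC exosomes (log2 fold change 5.00, SE 1.39), and 1700012I11Rik (-9.93, SE 2.14) in Fb exosomes. D230017M19Rik also missed the threshold without Fb replicate 2 (edgeR adjusted p = 0.0793). The TMM factors of this fit were 1.61 to 1.63 in the ESC libraries and 2.17, 0.232 and 0.467 in Fb replicates 1, 2 and 3, and with library totals alone the median log2 fold change moved from 0.07 to 0.80 and the calls became 205 higher in ESC and 151 in Fb exosomes. edgeR passed 0 RNAs without ESC replicate 1, 2 or 3 or Fb replicate 3 (560, 587, 625 and 617 at an unadjusted p under 0.05) and 591 without Fb replicate 1, while with all libraries DESeq2 passed 541 and limma 247.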

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

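The tRNA sums, the summed miR-199 and miR-486 pairs, the fit without tRNA genes, the size factors from the 100 most abundant RNAs, the shares of all assigned reads and the count of listed miRNAs without one library were chosen after the data were seen. Of 325 miRNAs tested 161 passed. That number was 96 when they were fitted with all other RNAs and adjusted over miRNAs alone, and 103 to 213 when a library was left out, with 107 without ESC replicate 3; the cause was not tested. Of the 54 named miRNAs that passed, 35 also passed without any one library, 17 lost the call without at least 1, and miR-142a-5p and miR-195a-5p were not tested in every such fit. For all RNAs (355 calls) DESeq2 gave 541, no count filter 697, at least 10 CPM in 3 libraries 213, and leaving out a library 0 to 591, and the cause was not tested. The labels do not say whether the replicate numbers pair the libraries. Same-numbered libraries deviated with r = -0.26, -0.11 and -0.13, and none correlated best with its own number. Other pairs ranged from -0.27 to 0.36, so with 3 libraries per group a shared batch cannot be excluded. With the replicate number as a block 114 miRNAs, 179 RNAs and 4 lists passed.

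Of the miRNA lists 4 passed camera, and 4 to 4 when a library was left out. With no count filter 9 passed, with an estimated correlation 1, and by fry, which asks only whether a list moves one way, 13. Listed miRNAs that passed numbered 69, with 83 without Fb replicate 1 and 51 to 65 without any other one library.

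As log2 ratios of mean shares of all assigned reads, without a fit, 10 named miRNAs that had passed on the Fb side turned to ESC, namely miR-24-3p (1.346), miR-22-3p (0.379), miR-615-3p (0.75), miR-29b-3p (0.658), miR-503-5p (0.299), miR-27a-3p (1.541), miR-23a-3p (0.809), miR-132-3p (1.638), miR-212-3p (1.068) and miR-206-3p (1.441). The larger miRNA share of ESC reads enters these ratios by construction, and miRNAs at 0 reads in a group had no ratio. Across the fits, the direction of a named miRNA turned only where it had not passed. On the log2 scale miR-29c-3p was at 0.09 with limma-trend, miR-126a-5p at 0.075 with no count filter, 0.044 without ESC replicate 2, 0.093 without Fb replicate 1 and 0.697 when fitted with all RNAs, miR-1a-3p at 2.201 without Fb replicate 1, and miR-192-5p at -0.30 with library totals only. Leaving out a library gave -0.557 to 0.093 for miR-126a-5p and -4.348 to 2.201 for miR-1a-3p, and these causes were not tested. The small nucleolar RNA difference was -0.0104 percentage points outside tRNA reads. The other class shares kept their direction when a library was left out, the miRNA difference at 12.1 to 12.9 points and the lncRNA difference at -12.1 to -8.04 points. Fb libraries had 49019 to 177990 miRNA reads, so 3 reads were 16.9 to 61.2 CPM there. The prior count of 2 entered the list tests and limma-trend, and no other prior count was tried.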

Other observations

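The families of the next paragraph and the tests on epithelial miRNAs and on Fb replicate 1 were chosen after the results were seen. The tests on the lncRNA share and the splits were set before.

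Among 8 further miRNA families, the miR-181 family, which acts in lymphocyte and vascular biology, stood out on the Fb side. It held 0.152% ± 0.0120 (SD, n = 3) of miRNA reads in ESC and 4.65% ± 0.138 in Fb exosomes. miR-181a-5p (log2 fold change -5.32, SE 0.33, edgeR adjusted p = 3.36e-05) and miR-181b-5p (-5.52, SE 0.32) were higher in Fb exosomes, and miR-181c-5p and miR-181d-5p did not pass (edgeR adjusted p = 0.0767 and 0.0910). The related miR-99b-5p and miR-100-5p went opposite ways, with log2 fold changes of 2.13 (SE 0.27) and -2.53 (SE 0.32). miR-99a-5p also passed on the Fb side (-1.40, SE 0.37, edgeR adjusted p = 0.0184). These calls compare shares of miRNA reads, and as shares of all assigned reads the groups overlapped for miR-100-5p. Of the miR-30 family, 2 of 5 members were higher in ESC exosomes, miR-30d-5p (log2 fold change 1.99, SE 0.27) and miR-30a-5p (1.35, SE 0.28). The vault RNA Vaultrc5 held 0.0433% ± 0.0173 of assigned reads in ESC and 0.00181% ± 0.00145 in Fb exosomes (log2 fold change 3.45, SE 0.98, edgeR adjusted p = 0.0487). That call was lost without any one ESC library or Fb replicate 3, and the families were tested with all 6 libraries only.

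Fb exosomes had a higher lncRNA share than ESC exosomes. Reads of annotated small RNA genes lying inside lncRNA spans are argued against as the sole source. Without the 380 lncRNA genes that span one, 5.735 of the 10.04 percentage points between the groups were left. Most of that remainder lay in few genes, with Gm16365 at 3.93% of assigned reads in Fb and 0.0126% in ESC exosomes. Gm26786 was at 1.44% and 0.00874%. Small RNA copies missing from the annotation cannot be seen by this test, so it does not decide whether such copies lie in these genes. A few genes taking most reads is a candidate explanation, as the 10 genes with the most Fb reads held at least 70.65% of the lncRNA reads of each Fb library. Without them the share was 1.45% ± 0.860 in Fb and 1.96% ± 0.138 in ESC exosomes, but choosing genes by Fb reads lowers the Fb side by construction. It was then 0.985% and 0.919% in Fb replicates 2 and 3. Fb replicate 1 was at 2.44%, still above every ESC library, so these genes did not hold all of its difference. Thinning the libraries to one depth moved no share by more than 0.008 points. Sampling fewer reads cannot move a share on average, so the number of reads alone would not give this difference. Thinning does not test other differences between the libraries that go with depth. These remain open, as do the cell type, donor mice and medium, untested.

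Fb exosomes held epithelial miRNAs at 1.06% of miRNA reads. Reads carried over from the ESC libraries, or ESC with the profile of these libraries among the Fb, would bring all members in the ratios of ESC. Among members of this list and the miR-183 cluster with a mean of at least 1000 ESC reads, the highest relative to ESC was at least 16.57 times the lowest in each Fb library, and in Fb replicate 2 miR-205-5p was at 4.05% of its ESC reads and miR-200c-3p at 0.245%. In Fb replicates 1 and 3 the lowest member rested on 1 read. Both are thus argued against as the sole source, while a part from either, epithelial cells of another profile and expression in Fb may remain. That part may not be small in Fb replicate 1. There miR-203-3p, miR-200c-3p, miR-429-3p, miR-183-5p and miR-182-5p were all at 0.169% to 0.270% of their ESC reads. Of the other members, miR-200b-3p was lower, and miR-200a-3p, miR-205-5p and miR-141-3p were higher.

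Fb replicate 1 had the lowest miRNA share of the Fb libraries. Only a depth below both other Fb libraries is argued against, since it had 7993503 assigned reads and replicate 3 had 6914504. These totals were known when the check was chosen. No biological explanation was tested, since the labels do not separate the Fb libraries.

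The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. Every split other than the real one mixes ESC and Fb libraries in both groups. The difference between ESC and Fb then counts as spread within a group and keeps the calls of single RNAs low. The counts of calls below therefore draw no line between the real grouping and chance. For miRNAs 1 split, the real one, gave as many as 161 calls, and the highest other gave 0. For all RNAs 1 split gave as many as 355, and the highest other gave 0. For lists 3 splits gave as many as 4, and the highest other gave 4.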
